A study of Homo sapiens with 16 samples.

How the data were processed

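Gene expression was measured by sequencing polyadenylated RNA of CCLP1 cells in 16 libraries, 8 groups of 2, deposited as 3 tables, 1 for each experiment. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to the hg19 build with TopHat, counted per gene with featureCounts and normalised with DESeq2. Versions, settings and strand handling are not given in the sources used here. The deposited values are a signal: gene counts divided by 1 size factor per library within a table, as the values themselves show. In each library 100% of values were whole multiples of a single step within a tolerance of 1e-06, so whole reads could be recovered. The size factors ran from 0.691 to 1.37 in experiment 1, 0.855 to 1.15 in experiment 2 and 0.853 to 1.17 in experiment 3. Because each table was scaled separately, tests were made within a table only.

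Libraries were assigned to groups from the labels. In experiment 1 they carry a clone number. In experiments 2 and 3 the columns show the group but no replicate number, and the libraries are called A and B in column order as names only. The control column of experiment 2 is named after a GFP virus while the labels call it empty, and the wording of the labels is used. The labels describe separate clones or infections for the 2 libraries of a group. The libraries of a group differed by far more than counting noise (chi-square per degree of freedom 19.5 to 669), so none was treated as a duplicate.

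Each table held 23368 lines, of which 28 had a date in place of a gene symbol, as spreadsheet software makes of some symbols. These were left out and held 0.208% to 0.276% of the reads of a library. Of the remaining 23340 symbols, 19653 were found in the gene name table at hand. The reference genome available was of another build than hg19, so no positions are printed. Libraries held 31222553 to 65370072 reads in genes in experiment 1, 20842954 to 28103162 in experiment 2 and 47366375 to 70064896 in experiment 3, with 15412 to 17195 genes detected. A group at 0 in both libraries was given a bound from a floor of 3 counts per library. That floor covers counting error only, since reads without molecular identifiers are not independent molecules.

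Because the values are normalised, the test was limma 3.58.1 (R 4.3.3) on log2(value + 1), with a pseudocount of 1, a fit of group means and empirical Bayes moderation with an intensity trend. Genes with at least 10 normalised counts in at least 2 libraries of a table were tested, and an adjusted p under 0.05 (Benjamini-Hochberg) was called. Experiments 1 and 2 were fitted with their 4 libraries each, and the 8 libraries of experiment 3 in 1 model with 4 comparisons and the interaction. With 2 libraries per group, exact rank tests cannot reach the threshold, and the p-values lean on the spread shared across genes. They measure only the spread between these libraries of a single cell line. The fit was tested on simulated data with genes changed by known folds. It recovered 81% of genes changed 2-fold in PRH overexpression, 67% and 73% for the PRH virus in control shRNA and NOTCH3 shRNA cells, 74% and 69% for the shRNA with the empty and the PRH virus, 51% for the interaction and 0% for PRH knockdown. Of the simulated calls 4.29% to 10.3% were false in the comparisons that made calls. The changed genes had a mean of at least 50, so recovery of the lower genes that were also tested is not covered. Base levels were means over all libraries of a table, so genes near absent from some groups of experiment 3 were simulated as present in all.

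The 25 gene lists were fixed before the data were examined: Notch receptors, ligands and machinery; Notch targets; G1/S and DNA replication; mitosis; CDK inhibitors; p53 targets. Mesenchymal and invasion genes, epithelial junction and keratin genes, and markers of cholangiocytes, hepatocytes, fibroblasts, endothelium and leukocytes formed further lists. The others held interferon-stimulated, NF-kB and inflammatory, VEGF and angiogenic, Wnt, TGF-beta and BMP, EGF-family and ERK, YAP/TAZ, hypoxia and glycolysis, unfolded protein and amino acid stress and cholesterol biosynthesis genes, mitochondrially encoded mRNAs and RNAs lacking a poly(A) tail. The mitochondrial list had fewer than 4 measured members and was not tested. Lists with at least 4 tested members entered camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists, and the same test with an estimated correlation was run beside it. NOTCH3 is in both Notch lists.

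Genes are named by a rule fixed before the data were examined. It takes HHEX and NOTCH3, and the 10 (for PRH knockdown, PRH overexpression and NOTCH3 shRNA with the empty virus) or 6 (for the other comparisons) higher and lower genes with the largest fold change. These had to pass the test, have a mean of at least 50 in a group and no overlap between the libraries of the groups. It also takes up to 4 members per direction of each list by smallest adjusted p, or, where none passed, up to 2 of smallest p given as values. Genes singled out otherwise are said to be chosen after their values were seen, and some genes that the rule picked are not reported here.

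Alternatives fixed before the data were examined were pseudocounts of 0.5 and 8, no filter and a mean of at least 50, rescaling to equal totals and with TMM, no variance trend, a 2-fold minimum, a replicate block in experiment 1, only the libraries of a comparison in the fit, each library left out in turn, the edgeR 4.0.16 quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, and for lists an estimated correlation and fry. Added after the data were seen were edgeR with the block, the Notch lists without NOTCH3, and PRH knockdown lists without the genes that mark the libraries labelled NOTCH3 shRNA. Those 231 genes had at least 20 CPM in both empty virus libraries labelled NOTCH3 shRNA and under 1% of that in control libraries. Overlaps give the genes called in both comparisons, the number for independent lists and the odds ratio of the 4 combinations of direction.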

Results

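The data are gene expression measurements by sequencing of polyadenylated RNA from CCLP1, an established human cell line of intrahepatic cholangiocarcinoma, a cancer of the bile ducts inside the liver. The 16 libraries form 8 groups of 2 in 3 experiments. Experiment 1 compared cells carrying a short hairpin RNA (shRNA, which lowers a chosen transcript) against PRH with cells carrying a control shRNA. PRH is a homeodomain transcription factor encoded by HHEX. Experiment 2 compared cells infected with an adenovirus that brings PRH with cells given an empty virus. Experiment 3 crossed an shRNA against NOTCH3, a receptor of the Notch pathway, with the PRH virus, so that cells with a control or a NOTCH3 shRNA each received the PRH or the empty virus. The libraries held 31222553 to 65370072 reads in genes in experiment 1, 20842954 to 28103162 in experiment 2 and 47366375 to 70064896 in experiment 3. Values are normalised counts, given as mean ± SD over the libraries of a group (n = 2), and fold changes are on the log2(value + 1) scale, which understates the change of low genes. Adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another tool is named.

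**Figure D1:**
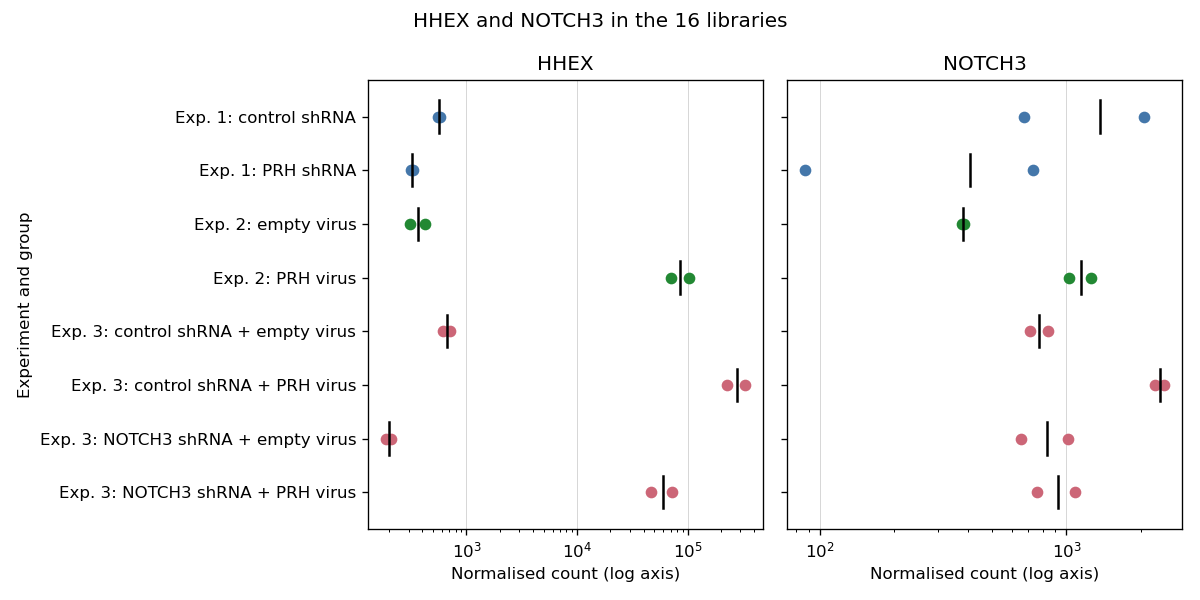
Normalised counts of HHEX and NOTCH3 (horizontal log axes) in the 16 libraries, by experiment and group. Each point is a library, each vertical line the mean of the 2 libraries of a group, and colours mark the experiment. HHEX stood at 279700.0 ± 71729.5 with the PRH virus in control shRNA cells, and NOTCH3 ranged from 86.8 to 729 in the PRH shRNA libraries.

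The first comparison asked what changes when PRH is lowered. HHEX stood at 319.9 ± 8.36 against 567 ± 18.2 (PRH shRNA against control shRNA, SD, n = 2), a log2 fold change of -0.82 that did not pass the test (adjusted p = 0.9999). NOTCH3 stood at 86.8 and 729 in PRH shRNA clones 1 and 2, and at 672 and 2065 in control clones 1 and 2. Its log2 fold change of -2.22 did not pass either (adjusted p = 0.9999), except without PRH shRNA clone 2, where it was -3.75 with an adjusted p of 0.00481. The genes with the smallest p, singled out after their values were seen, were POSTN, a matrix protein of stromal cells, at 0.723 ± 1.02 against 3986 ± 636, and CALB2, which encodes the calcium-binding protein calretinin, at 19.4 ± 13.1 against 16144 ± 6773 (adjusted p = 0.0960 for both). None of the 14511 genes tested passed with limma, while 959 had an unadjusted p under 0.05 where 726 lie by chance. The quasi-likelihood test of edgeR called 0 genes, with 1024 at an unadjusted p under 0.05, and DESeq2 called 703 genes, 601 higher and 102 lower. On simulated data of this spread the same fit recovered 0% of genes changed 4-fold, so the design says little about single genes. Leaving out 1 library let genes pass: 781 without PRH shRNA clone 1, 186 without PRH shRNA clone 2, 156 without control clone 1 and 32 without control clone 2.

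Gene lists, tested with camera, set the PRH shRNA libraries apart in 10 of 24 lists at the preset correlation and in 0 with an estimated correlation; 6 lists were called without control clone 2. In the epithelial junction and keratin list, 32 of 33 members lay above 0 in log2 fold change (adjusted p = 2.31e-29, and adjusted p = 0.467 with an estimated correlation), and 0 passed over all genes while 21 were higher adjusted over the list alone. ELF3, an epithelial transcription factor, stood at 2609 ± 2082 against 128 ± 24.7 and EPCAM, an epithelial adhesion molecule, at 7333 ± 3256 against 607 ± 519.6. Of the 15 cholangiocyte markers, 9 were higher adjusted over the list alone and 0 over all genes (adjusted p = 5.37e-09, and adjusted p = 0.467 with an estimated correlation). KRT19, a bile duct keratin, stood at 10040.2 ± 8945 against 546 ± 153. In the same libraries, 231 genes that mark the libraries labelled NOTCH3 shRNA of experiment 3 stood at a median of 45.0% of their level there in PRH shRNA clone 2, 9.47% in clone 1 and 1.09% to 1.84% in the control clones. Without these genes, left out after the data were seen, 11 lists were called. That does not free the lists of this profile, since 2875 genes were called at least 2-fold higher in the libraries labelled NOTCH3 shRNA with the empty virus.

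The list of 11 Notch target genes was called lower (adjusted p = 0.00208, and adjusted p = 0.755 with an estimated correlation), with 3 members above 0 in log2 fold change and 1 lower adjusted over the list alone. HEY2, a Notch-induced repressor, stood at 3.43 ± 0.755 against 538 ± 56.0 and DTX1, a Notch regulator, at 2.48 ± 3.501 against 69.1 ± 57.4. The Notch receptor, ligand and machinery list was not called (adjusted p = 0.449). Of 18 mesenchymal and invasion genes, 1 was lower adjusted over the list alone (adjusted p = 0.0277, and adjusted p = 0.640 with an estimated correlation). CDH2, the mesenchymal cadherin, stood at 23.0 ± 30.5 against 2368 ± 550.2. Of 15 fibroblast markers, 5 were lower adjusted over the list alone (adjusted p = 5.31e-06, and adjusted p = 0.467 with an estimated correlation), among them DCN, the matrix proteoglycan decorin, at 6.44 ± 9.10 against 329 ± 106. No member of these lists passed over all genes.

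Lists called higher were the 27 interferon-stimulated genes (adjusted p = 6.86e-06, and adjusted p = 0.640 with an estimated correlation), with OAS1, an antiviral enzyme, at 369 ± 283 against 19.0 ± 13.4, and the 22 NF-kB and inflammatory genes (adjusted p = 0.000881, and adjusted p = 0.467 with an estimated correlation). The latter had a median log2 fold change of -0.00 beside a mean of 1.51, and 5 members were higher adjusted over the list alone. IL8, a neutrophil chemokine, stood at 3627 ± 4138 against 16.5 ± 3.67 and CXCL5, a related chemokine, at 6225 ± 2622 against 588 ± 349.8. The 25 cholesterol biosynthesis genes (adjusted p = 0.00529, and adjusted p = 0.755 with an estimated correlation), the 5 measured endothelial markers (adjusted p = 0.0165, and adjusted p = 0.467 with an estimated correlation) and the 10 measured leukocyte markers (adjusted p = 0.00285, and adjusted p = 0.467 with an estimated correlation) were called higher as well, with 0 members passing over all genes or adjusted over the list alone. ERG, an endothelial transcription factor, stood at 29.5 ± 9.47 against 5.34 ± 4.86 and LCP1, an actin-bundling protein of leukocytes, at 218 ± 175 against 21.9 ± 31.0. Rescaling to equal totals moved the median log2 fold change of all genes from -0.07 to 0.03.

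Leaving out 1 library changed calls of single genes in this comparison, each time with a lone library in 1 group that is assumed to vary like the other group. POSTN, CALB2, HEY2, CDH2 and IL8 passed whichever of the 4 libraries was left out, at adjusted p-values up to 0.0296. EPCAM, DCN, CXCL5 and LCP1 passed in the fits without PRH shRNA clone 1, PRH shRNA clone 2 or control clone 1 (up to 0.0452). ELF3 and KRT19 passed without PRH shRNA clone 1 or control clone 1 (up to 0.0455), OAS1 without PRH shRNA clone 1 (0.000138) and DTX1 without PRH shRNA clone 2 (0.000550).

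The second comparison asked what PRH does when it is brought in by virus. HHEX stood at 85981 ± 22642 against 365 ± 81.6 (PRH virus against empty virus, SD, n = 2; log2 fold change 7.87, adjusted p = 4.40e-05), where reads from the virus and from the cells' own gene cannot be told apart. NOTCH3 rose from 379 ± 3.81 to 1143 ± 162 (1.58, adjusted p = 0.00281). CCL5, a chemokine, rose from 0.585 ± 0.827 to 199 ± 111, PTGES, which makes prostaglandin E2, rose from 2.80 ± 2.31 to 67.0 ± 38.2, and C3, a complement component, rose from 1.76 ± 2.48 to 68.0 ± 56.8. GRM4, a glutamate receptor, BCAM, a laminin receptor, ENTPD2, an ectonucleotidase, LPIN3, a phosphatidate phosphatase, CYP4F22, a fatty acid hydroxylase, and GALNT6, a glycosyltransferase, rose by log2 fold changes of 3.95 to 4.98. Among the genes that fell, HSPA6, a stress-induced HSP70 chaperone, went from 2464 ± 1629 to 15.8 ± 1.47, and HSPA1B, whose reads cannot be fully separated from its near-identical copy, from 169.5 ± 56.5 to 19.8 ± 7.11. FOXP2 and RORB, transcription factors, had log2 fold changes of -3.05 and -2.57. CPA4, a carboxypeptidase, RAPGEF4, a cAMP sensor, MLLT11, LRRN3, SEMA3E, a guidance ligand, and CD36, a fatty acid transporter, fell with log2 fold changes of -2.24 to -3.15. Without empty virus library A, CPA4, RAPGEF4 and CD36 no longer passed (adjusted p = 0.0687, 0.131 and 0.186).

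In the Notch receptor, ligand and machinery list, 6 of 25 measured members rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0166, and adjusted p = 0.657 with an estimated correlation). JAG2, a Notch ligand, rose by 1.15 on the log2 scale, LFNG, a glycosyltransferase that modifies Notch, by 1.99, PSEN2, a gamma-secretase subunit, by 0.92 and NOTCH1, a receptor, by 0.93. Of the 10 Notch target genes, NOTCH3 itself among them, 5 rose and 0 fell, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.0542). HEYL and HES1, repressors induced by Notch, rose by 1.88 and 1.64. Of the interferon-stimulated genes, 5 of 17 measured members rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.0166, and adjusted p = 0.851 with an estimated correlation), with DDX58, a sensor of viral RNA, at 1.93 and ISG20, an exonuclease, at 1.71. Of the cholesterol biosynthesis genes, 8 of 24 measured members rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.0166, and adjusted p = 0.657 with an estimated correlation), with DHCR7, a sterol reductase, up by 0.59. STARD4, a sterol carrier, had a log2 fold change of -0.61.

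In this comparison 2073 of 13263 genes tested passed, 1313 higher and 760 lower, of which 778 differed by at least 2-fold. The count was 1314 without PRH virus library A and 1354 without empty virus library A. It was 758 without the intensity trend in the variance and 1382 with no filter on low values. The camera test called 3 of 21 lists, and 6 without PRH virus library A and 5 without PRH virus library B.

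The same virus was given to control shRNA cells in experiment 3. HHEX stood at 279700.0 ± 71729.5 against 664 ± 72.3 (PRH virus against empty virus, SD, n = 2; log2 fold change 8.70, adjusted p = 1.75e-07). NOTCH3 rose from 775 ± 90.0 to 2392 ± 137 (1.63, adjusted p = 0.00120). PADI3, a peptidylarginine deiminase, was at 0 in both empty virus libraries and at 332 ± 35.4 with the PRH virus, at least 103-fold higher against a floor of 3 counts per library. PTGES rose from 5.12 ± 7.25 to 618 ± 118 and MLXIPL, a glucose-responsive transcription factor, from 2.05 ± 2.90 to 220.1 ± 36.7. MT1B, a metallothionein whose reads are shared with near copies, and PRRT4 rose by 6.65 and 6.54 on the log2 scale. LOC729987, LRTM2, CPA4, GRIA4, a glutamate receptor subunit, XIRP2, an actin-binding protein, and TACR1, the substance P receptor, fell with log2 fold changes of -4.19 to -5.08. None of these 6 calls held in every fit with a library left out. LRTM2, CPA4 and GRIA4 lost their calls whichever of the 4 libraries of the comparison was left out (log2 fold changes of -3.50 to -6.26, adjusted p = 0.0576 to 0.219). LOC729987, XIRP2 and TACR1 lost theirs without either empty virus library or PRH virus library B (-2.30 to -5.14, adjusted p = 0.0520 to 0.257). HSPA6 did not pass here (log2 fold change 1.09, adjusted p = 0.365).

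In the Notch receptor, ligand and machinery list, 11 of 27 measured members rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 0.00916, and adjusted p = 0.569 with an estimated correlation). JAG2 rose by 1.91 on the log2 scale, NOTCH1 by 1.74 and RBPJ, the DNA-binding partner of cleaved Notch, by 0.86, while ADAM10, the protease that cleaves Notch, had a log2 fold change of -0.58. Of the Notch target genes, 7 of 10 measured members rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.00707, and adjusted p = 0.569 with an estimated correlation). HES2 rose by 1.89, DTX4, a ubiquitin ligase of the pathway, by 1.51 and NRARP, a feedback inhibitor, by 0.87. Among interferon-stimulated genes, 15 of 29 measured members rose and 0 fell (16 and 0 adjusted over the list alone; adjusted p = 0.000152, and adjusted p = 0.569 with an estimated correlation). OAS3, an antiviral enzyme, rose by 3.11 and ISG15, a ubiquitin-like protein, by 1.14. Among NF-kB and inflammatory genes, 11 of 29 measured members rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.0458, and adjusted p = 0.569 with an estimated correlation), with LIF, a cytokine, at 3.67 and IL32, an inflammatory mediator, at 4.61.

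**Figure D2:**
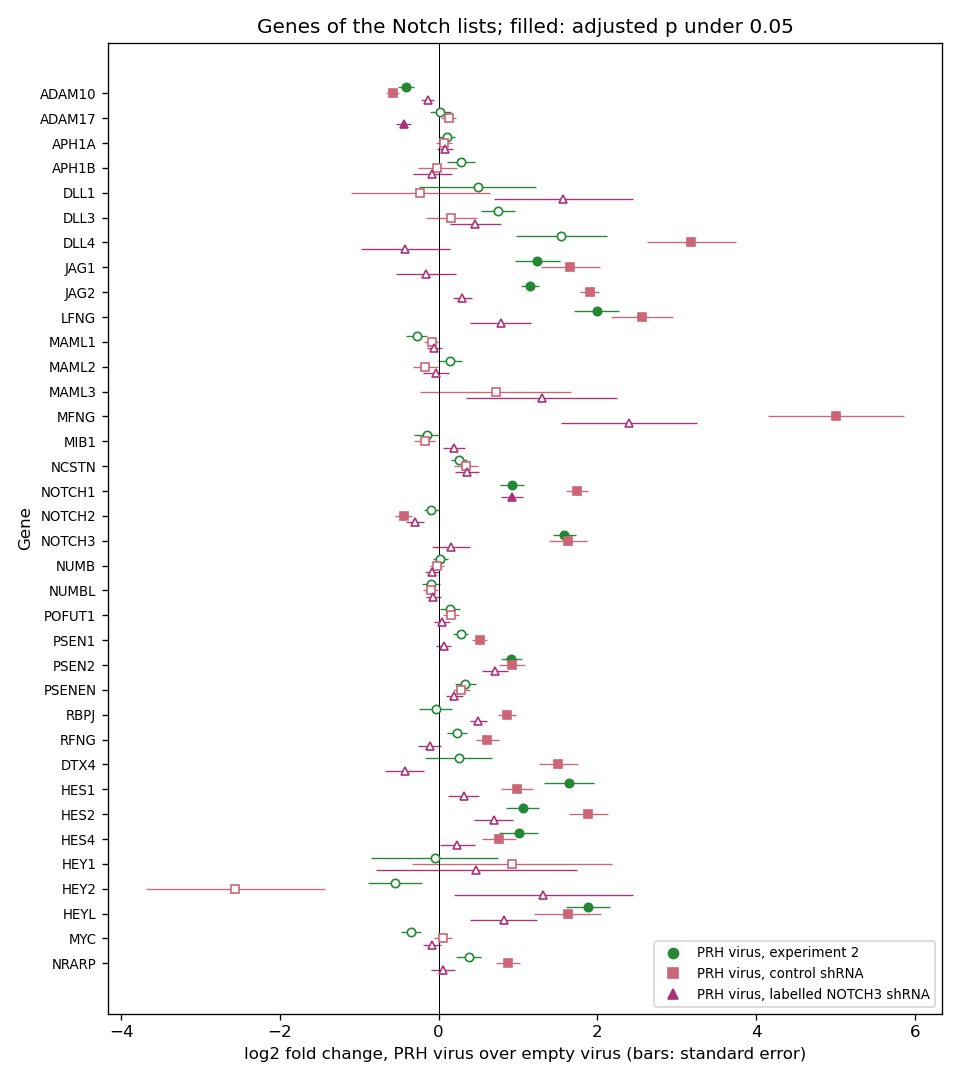
Log2 fold change (horizontal axis) with its standard error (bars) of the measured genes of both Notch lists, PRH virus over empty virus, in experiment 2 (circles), in control shRNA cells (squares) and in cells labelled NOTCH3 shRNA (triangles). Filled symbols passed at an adjusted p under 0.05. NOTCH3 had log2 fold changes of 1.58, 1.63 and 0.15 in these comparisons.

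In the hypoxia and glycolysis list, 8 of 27 measured members rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 0.00814, and adjusted p = 0.569 with an estimated correlation), with LOXL2, a collagen crosslinking enzyme, at 2.18 and SLC2A1, a glucose transporter, at 1.32. In the unfolded protein and amino acid stress list, 11 of 30 measured members rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.0458, and adjusted p = 0.569 with an estimated correlation), with HYOU1, an endoplasmic reticulum chaperone, at 0.60. Among YAP/TAZ targets, 1 of 24 measured members rose and 7 fell (1 and 7 adjusted over the list alone; adjusted p = 0.0458, and adjusted p = 0.610 with an estimated correlation), with NT5E, an ectonucleotidase, at -1.69 and TGFB2, a growth factor, at -0.87. In the cholesterol biosynthesis list, 1 of 25 measured members rose and 9 fell (1 and 9 adjusted over the list alone; adjusted p = 0.00470, and adjusted p = 0.685 with an estimated correlation), with MSMO1 at -1.05. The direction of this list was opposite to that in experiment 2. Of 19 RNAs without a poly(A) tail, 0 rose and 6 fell (0 and 6 adjusted over the list alone; adjusted p = 0.00182, and adjusted p = 0.569 with an estimated correlation). HIST1H3B and HIST1H3D, histone genes whose near-identical copies make their counts uncertain, had log2 fold changes of -3.56 and -2.75.

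In control shRNA cells 4282 of 15836 genes tested passed, 2412 higher and 1870 lower, 1738 of them by at least 2-fold. Of the changed genes 56.3% were higher, and 70.0% after rescaling to equal totals. The count was 2208 without empty virus library A, 2605 without empty virus library B, 2453 without PRH virus library B and 2730 without the variance trend. The lists called numbered 9 of 24, and 6 without PRH virus library B. Between experiment 2 and control shRNA cells, 1618 genes passed in both, 1073 higher in both and 539 lower in both, against 223 and 102 for independent lists, and 99.6% had the same direction. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.771.

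In cells labelled NOTCH3 shRNA the PRH virus was compared with the empty virus, to ask whether the response needs NOTCH3. HHEX stood at 59243 ± 17914 against 198 ± 15.6 (SD, n = 2; log2 fold change 8.19, adjusted p = 3.04e-07). NOTCH3 stood at 923 ± 229.5 against 836 ± 257 and did not pass (0.15, adjusted p = 0.799). LGI3, a secreted protein of the nervous system, was at 0 in both empty virus libraries and at 86.5 ± 20.2 with the PRH virus, at least 28.8-fold higher. STAC2, SLC8A2, a sodium-calcium exchanger, GABRD, a GABA receptor subunit, and C16orf11 rose by log2 fold changes of 3.75 to 4.90. HIST1H3B, NCAM2, an adhesion molecule, FOXP2, PLSCR4, PAPSS2, a sulfate donor synthase, and WNT5B, a Wnt ligand, fell, with log2 fold changes of -0.97 to -3.61. NOTCH1 rose by 0.92 and ADAM17, a protease of Notch, had a log2 fold change of -0.44. The 2 Notch lists were not called (adjusted p = 0.136 for the machinery and 0.325 for the targets).

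Among mesenchymal and invasion genes, 3 rose and 0 fell of 21 (6 and 0 adjusted over the list alone; adjusted p = 0.00365, and adjusted p = 0.330 with an estimated correlation), with ITGA5, a fibronectin receptor subunit, at 1.08. Among fibroblast markers, 2 rose and 0 fell of 13 (4 and 0 adjusted over the list alone; adjusted p = 0.00293, and adjusted p = 0.330 with an estimated correlation), with THY1, a surface glycoprotein, at 1.11. Among TGF-beta and BMP targets, 2 rose and 0 fell of 21 (7 and 1 adjusted over the list alone; adjusted p = 0.00293, and adjusted p = 0.330 with an estimated correlation), with TGFB1 itself at 0.80. In the unfolded protein and amino acid stress list, 0 rose and 2 fell of 30 (0 and 3 adjusted over the list alone; adjusted p = 3.13e-07, and adjusted p = 0.330 with an estimated correlation), with SLC7A11, a cystine transporter, at -0.85 and HYOU1 at -0.39. Of the RNAs without a poly(A) tail, 0 rose and 2 fell of 19 (0 and 3 adjusted over the list alone; adjusted p = 0.00323, and adjusted p = 0.330 with an estimated correlation). For 3 further called lists no member passed over all genes: mitosis, higher (1 and 0 adjusted over the list alone; adjusted p = 0.00293, and adjusted p = 0.790 with an estimated correlation), epithelial junction and keratin genes, lower (0 and 0 adjusted over the list alone; adjusted p = 0.00786, and adjusted p = 0.716 with an estimated correlation), and cholesterol biosynthesis, lower (0 and 4 adjusted over the list alone; adjusted p = 1.39e-05, and adjusted p = 0.716 with an estimated correlation). CDC25C, a mitotic phosphatase, stood at 1086 ± 281 against 513 ± 46.8 and OCLN, a tight junction protein, at 2043 ± 150.1 against 2732 ± 397.

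Here 350 of 15836 genes passed, 301 higher and 49 lower, 192 of them by at least 2-fold. The count was 1, HHEX, without either PRH virus library, 92 without empty virus library A, 3 with only the 4 libraries of the comparison in the fit, 82 without the variance trend and 1097 with DESeq2. Of the calls named for this comparison, all but that of HHEX were lost without PRH virus library A (adjusted p = 0.0688 to 0.155) and without PRH virus library B (adjusted p = 0.119 to 0.372). Without empty virus library A those of SLC8A2, HIST1H3B, NCAM2, FOXP2, PLSCR4, PAPSS2, WNT5B, NOTCH1, ADAM17, THY1, SLC7A11 and HYOU1 were lost too (adjusted p = 0.0530 to 0.169). Without library B those of NCAM2, FOXP2, PLSCR4, PAPSS2, WNT5B, ADAM17 and HYOU1 were lost (adjusted p = 0.0790 to 0.126). Of the genes that passed here, 256 also passed in control shRNA cells, 216 higher in both and 26 lower in both, against 45.8 and 5.79 for independent lists, and 94.5% had the same direction. Both calls used the same variance per gene, which can favour a call in both, so the numbers for independent lists can be too low. The correlation across genes, which are not independent replicates, was r = 0.298. Between single libraries of these cells, PRH virus library A correlated with empty virus library A at r = 0.9752 and with PRH virus library B at r = 0.964, while PRH virus library B correlated with empty virus libraries A and B at r = 0.950 and r = 0.946.

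The libraries labelled NOTCH3 shRNA were compared with control shRNA libraries under the empty virus. NOTCH3 was not lower there: it stood at 836 ± 257 against 775 ± 90.0 (SD, n = 2), a log2 fold change of 0.08 with a 95% interval from -0.46 to 0.62 (adjusted p = 0.798). The direction of this difference reversed without NOTCH3 shRNA library B (-0.24) and without control library A (-0.04), and the label is used only as a name for these libraries. HHEX stood at 198 ± 15.6 against 664 ± 72.3 (-1.74, adjusted p = 0.000126). FAM84A and C12orf59 were at 0 in both control libraries and at 6239.6 ± 2071 and 5932 ± 671 in the libraries labelled NOTCH3 shRNA, at least 1929-fold and 1834-fold higher. CDH17, a cadherin of intestinal and bile duct tumours, stood at 9833 ± 2484 against 1.02 ± 1.45, AGR2, a protein disulfide isomerase of mucous epithelia, at 12712 ± 2637 against 5.09 ± 7.20, and SLC6A20, a proline transporter, KCNE3, a potassium channel subunit, CYP2J2, a cytochrome, ASCL2, a stem cell transcription factor, EPDR1 and ERN2, an endoplasmic reticulum stress sensor of epithelia, rose by log2 fold changes of 11.15 to 11.66. SEZ6, a neuronal membrane protein, fell from 16648 ± 587 to 11.4 ± 3.28, CXCL6, a chemokine, from 4149 ± 958 to 3.14 ± 2.01 and CDH11, a mesenchymal cadherin, from 1551 ± 193 to 7.02 ± 8.32. DPPA2, A1CF, NLRP10, TMEFF2, GPR158, PCDH15 and FLRT2 fell with log2 fold changes of -6.85 to -9.72.

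Among the epithelial junction and keratin genes, 31 rose and 0 fell of 33 (31 and 0 adjusted over the list alone; adjusted p = 1.11e-16, and adjusted p = 0.303 with an estimated correlation). EPCAM stood at 31148 ± 4390.3 against 21.3 ± 9.86, PKP3, a desmosomal protein, at 11076 ± 1437 against 46.4 ± 3.24 and CLDN4, a tight junction claudin, at 13680.3 ± 1268 against 72.6 ± 14.2. Among cholangiocyte markers, 14 rose and 2 fell of 18 (14 and 3 adjusted over the list alone; adjusted p = 0.000363, and adjusted p = 0.303 with an estimated correlation), with KRT19 at 57566 ± 8763 against 33.4 ± 31.2 and CFTR, a chloride channel of bile ducts, at 2211 ± 983 against 0 ± 0. Among mesenchymal and invasion genes, 5 rose and 12 fell of 21 (6 and 13 adjusted over the list alone; adjusted p = 0.0316, and adjusted p = 0.511 with an estimated correlation). FN1, fibronectin, and VIM, vimentin, had log2 fold changes of -2.89 and -1.83, while TNC, a matrix protein, and CDH2 rose by 8.96 and 6.08. Across genes, which are not independent replicates, libraries labelled NOTCH3 shRNA and control libraries correlated with r = 0.792 to 0.838, against 0.964 to 0.980 within the groups of experiment 3. Marker genes chosen for being abundant in the libraries labelled NOTCH3 shRNA and under 1% of that in control libraries numbered 231, and the converse rule gave 4.

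**Figure D3:**
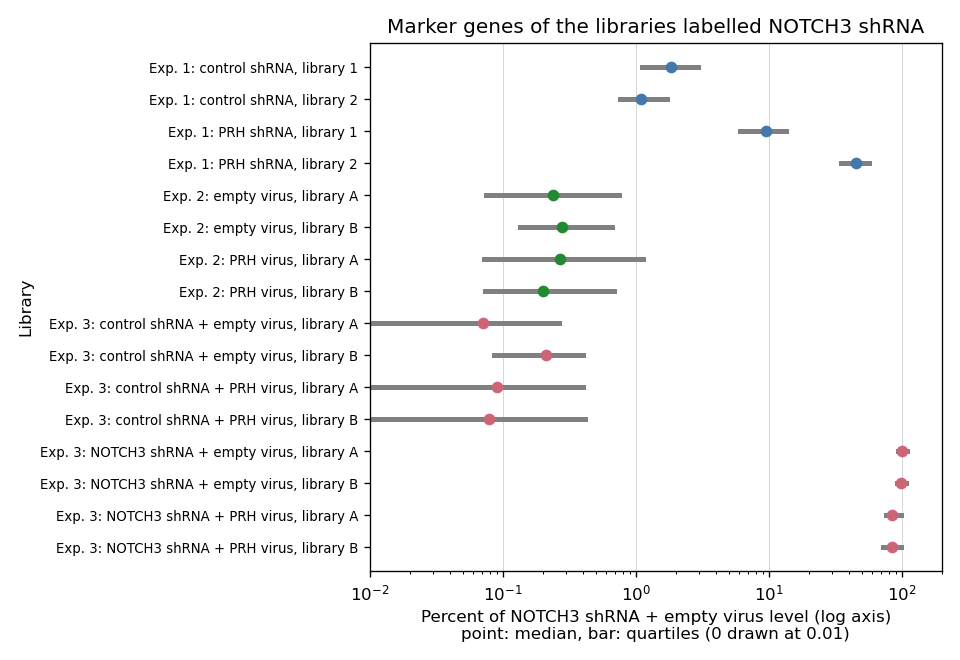
Level of 231 marker genes of the libraries labelled NOTCH3 shRNA (empty virus) in each of the 16 libraries, as a percent of their level in those libraries (horizontal log axis). Points are medians over the genes and bars run between the quartiles. The medians were 45.0% in PRH shRNA clone 2 and 9.47% in clone 1, and at most 1.84% in the control shRNA libraries.

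Among interferon-stimulated genes, 21 rose and 3 fell of 29 (21 and 3 adjusted over the list alone; adjusted p = 0.000488, and adjusted p = 0.511 with an estimated correlation), with OAS3 at 10.18 and IFI35 at -3.68 on the log2 scale. Among Wnt targets, 12 rose and 2 fell of 20 (13 and 2 adjusted over the list alone; adjusted p = 0.00822, and adjusted p = 0.303 with an estimated correlation), with LEF1, a Wnt effector, at 10.65 and DKK1, a Wnt inhibitor, at -2.05. In the hypoxia and glycolysis list, 12 rose and 2 fell of 27 (13 and 2 adjusted over the list alone; adjusted p = 0.0316, and adjusted p = 0.511 with an estimated correlation), with SLC2A1 at 4.95. In the unfolded protein and amino acid stress list, 17 rose and 1 fell of 30 (18 and 1 adjusted over the list alone; adjusted p = 0.00822, and adjusted p = 0.511 with an estimated correlation), with HYOU1 at 1.77. In the cholesterol biosynthesis list, 22 rose and 2 fell of 25 (22 and 2 adjusted over the list alone; adjusted p = 6.12e-06, and adjusted p = 0.511 with an estimated correlation), with MSMO1 at 3.01 and STARD4 at -0.99. The Notch lists were not called (adjusted p = 0.947 for the machinery and 0.347 for the targets). JAG1, a Notch ligand, rose by 7.28, HES1 rose by 3.40 and NOTCH1 had a log2 fold change of -0.86. In all, 8221 of 15836 genes passed, 4570 higher and 3651 lower, of which 4466 differed by at least 2-fold and 1392 by at least 16-fold.

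With the PRH virus, NOTCH3 was lower in the libraries labelled NOTCH3 shRNA, at 923 ± 229.5 against 2392 ± 137 (SD, n = 2; log2 fold change -1.39, adjusted p = 0.00118), and so was HHEX, at 59243 ± 17914 against 279700.0 ± 71729.5 (-2.25, adjusted p = 3.61e-05). KRT19 stood at 52522 ± 6.20 against 1.39 ± 0.764 and EHF, an epithelial transcription factor, at 9560.3 ± 413 against 0.483 ± 0.683. CDH17 and TMEM200A were at 0 in both control libraries, at least 3007-fold and 2586-fold higher, and ABCB1, a drug efflux pump, stood at 11396 ± 2065 against 0.966 ± 1.37. SEZ6, CXCL6, DPPA2, CDH11, PPP1R14A, an inhibitor of myosin phosphatase, and TMEFF2 fell, with log2 fold changes of -6.71 to -9.88.

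Among epithelial junction and keratin genes, 31 rose and 1 fell of 33 (31 and 1 adjusted over the list alone; adjusted p = 1.25e-16, and adjusted p = 0.271 with an estimated correlation), with EPCAM at 12.23. Among cholangiocyte markers, 14 rose and 2 fell of 18 (14 and 2 adjusted over the list alone; adjusted p = 3.23e-05, and adjusted p = 0.271 with an estimated correlation), with CFTR at 10.64. Among Wnt targets, 12 rose and 4 fell of 20 (12 and 4 adjusted over the list alone; adjusted p = 0.0256, and adjusted p = 0.286 with an estimated correlation), with APCDD1, a Wnt inhibitor, at 10.62. Among TGF-beta and BMP targets, 11 rose and 4 fell of 21 (12 and 4 adjusted over the list alone; adjusted p = 0.0408, and adjusted p = 0.499 with an estimated correlation), with TGFBI, a matrix protein, at 9.90 and TGFB1 at -1.38. Among cholesterol biosynthesis genes, 22 rose and 2 fell of 25 (22 and 2 adjusted over the list alone; adjusted p = 3.36e-07, and adjusted p = 0.649 with an estimated correlation). Among p53 targets, 4 rose and 9 fell of 23 (4 and 10 adjusted over the list alone; adjusted p = 0.0403, and adjusted p = 0.286 with an estimated correlation), with SESN2, a stress-induced regulator, at -2.07 and CDKN1A, an inhibitor of cell cycle kinases, at -1.49. In all, 7472 of 15836 genes passed, 4132 higher and 3340 lower, of which 3703 differed by at least 2-fold and 1208 by at least 16-fold. The lists called numbered 6 of 24, and 4 without NOTCH3 shRNA + PRH virus library A or without control shRNA + PRH virus library B.

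The interaction of virus and shRNA tested whether the response to the PRH virus differed between the libraries labelled NOTCH3 shRNA and control shRNA libraries (n = 2 per group). Its value is the log2 fold change with the PRH virus in the former minus that in the latter, so a positive value can come from a weaker fall and a negative value from a weaker rise. The interaction of HHEX did not pass (-0.51, adjusted p = 0.366), and that of NOTCH3 was negative (-1.47, adjusted p = 0.0279). That call was lost without any single library other than NOTCH3 shRNA + empty virus library A (adjusted p = 0.0514 to 0.116). PTGES, FUT1, a fucosyltransferase, LOC100130238, PRRT4, HERC5, an interferon-induced ligase, and BCAM had interaction values of -6.04 to -7.20, and the values of ADAMTS6, a metalloprotease, KRTAP3-2, SHROOM2, an actin-binding protein, ANKRD20A4, PCDH9, a protocadherin, and NDP, a Wnt receptor ligand, were 4.19 to 5.33. KRTAP3-2 and ANKRD20A4 belong to families with near copies and are uncertain. KRTAP3-2 kept its call only without NOTCH3 shRNA + empty virus library A among the 8 libraries (adjusted p of the other fits 0.0571 to 0.134). ANKRD20A4 and PRRT4 kept theirs only without NOTCH3 shRNA + PRH virus library A (0.0784 to 0.178), and HERC5 only without NOTCH3 shRNA + empty virus library B or control shRNA + PRH virus library A (0.0650 to 0.115). PTGES lost its call without NOTCH3 shRNA + PRH virus library A or B (adjusted p = 0.0502 and 0.0613), NDP without the former (0.0575), and ADAMTS6 without the latter (0.0620) or control shRNA + empty virus library B (0.0539).

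In the Notch receptor, ligand and machinery list, 0 of 27 members had a positive and 5 a negative interaction that passed (1 and 9 adjusted over the list alone; adjusted p = 0.0315, and adjusted p = 0.470 with an estimated correlation), and among Notch targets 0 of 10 members had a positive and 3 a negative interaction that passed (0 and 4 adjusted over the list alone; adjusted p = 0.0140, and adjusted p = 0.470 with an estimated correlation). JAG2 had an interaction of -1.61. Without NOTCH3 in these lists, a choice made after the data were seen, 9 of 24 lists were called in place of 10. That choice alters the Notch lists alone, so a Notch list lost its call, and which of them is not given here. Among interferon-stimulated genes, 0 of 29 members had a positive and 7 a negative interaction that passed (1 and 8 adjusted over the list alone; adjusted p = 0.000169, and adjusted p = 0.470 with an estimated correlation), with OAS3 at -3.60 and ISG15 at -1.17. In the unfolded protein and amino acid stress list, 0 of 30 members had a positive and 10 a negative interaction that passed (0 and 14 adjusted over the list alone; adjusted p = 1.48e-06, and adjusted p = 0.470 with an estimated correlation), with HYOU1 at -0.99 and CHAC1, a glutathione-degrading enzyme, at -1.29. Among NF-kB and inflammatory genes, 0 of 29 members had a positive and 4 a negative interaction that passed (1 and 7 adjusted over the list alone; adjusted p = 0.0155, and adjusted p = 0.470 with an estimated correlation), with LIF at -3.83. In the hypoxia and glycolysis list, 2 of 27 members had a positive and 3 a negative interaction that passed (2 and 7 adjusted over the list alone; adjusted p = 0.00232, and adjusted p = 0.470 with an estimated correlation), with P4HA2, a collagen prolyl hydroxylase, at -1.62 and SLC2A1 at -1.34.

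Among YAP/TAZ targets, 4 of 24 members had a positive and 1 a negative interaction that passed (6 and 1 adjusted over the list alone; adjusted p = 0.00477, and adjusted p = 0.470 with an estimated correlation), with NT5E at 1.39 and TGFB2 at 1.15. Among epithelial junction and keratin genes, 1 of 33 members had a positive and 6 a negative interaction that passed (1 and 7 adjusted over the list alone; adjusted p = 0.00993, and adjusted p = 0.470 with an estimated correlation), with F11R, a junctional adhesion molecule, at -2.66 and PKP3 at -1.88. In the list of G1/S and DNA replication genes, 0 of 34 members had a positive and 2 a negative interaction that passed (0 and 1 adjusted over the list alone; adjusted p = 0.0351, and adjusted p = 0.558 with an estimated correlation), and in the mitosis list 1 of 32 members had a positive and 0 a negative interaction that passed (0 and 0 adjusted over the list alone; adjusted p = 0.00197, and adjusted p = 0.477 with an estimated correlation). The test called 1329 of 15836 genes, 551 with a positive and 778 with a negative interaction, and 778 of all 1329 by at least 2-fold. The size of the log2 fold change, whatever its sign, was smaller in the libraries labelled NOTCH3 shRNA for 1250 of them and larger for 79. The count was 721 and 499 without NOTCH3 shRNA + PRH virus libraries A and B, 853 without NOTCH3 shRNA + empty virus library A, 730 without control shRNA + PRH virus library B, and 668 and 873 without control shRNA + empty virus libraries A and B. It was 351 without the variance trend and 2212 with DESeq2, and 6 lists were called without control shRNA + empty virus library A.

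The other overlaps were computed between comparisons of different experiments. The log2 fold changes of PRH knockdown and PRH overexpression correlated with r = -0.0402 across genes, which are not independent replicates, and no gene passed in both because none passed in the knockdown. PRH knockdown and the libraries labelled NOTCH3 shRNA (empty virus) correlated with r = 0.716 across genes. PRH overexpression and the libraries labelled NOTCH3 shRNA shared 1353 called genes, 58.5% in the same direction: 449 higher in both, 343 lower in both, 415 higher with PRH and lower in the libraries labelled NOTCH3 shRNA, and 146 the other way. Independent lists would share 340, 205, 354 and 196.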

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

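The tests of a larger spread and of genes already at their level were fixed before their results were seen, while those of the genes starting below their control level and of the virus dose were chosen after. The response to the PRH virus differed between the libraries labelled NOTCH3 shRNA and control shRNA libraries, by the interaction test of limma, for 1329 genes, and NOTCH3 was not lower in the former with the empty virus. Of the 10 lists whose response differed, 8 had lower log2 fold changes in the libraries labelled NOTCH3 shRNA: Notch receptors, ligands and machinery (0.0315), Notch target genes (0.0140), G1/S and DNA replication (0.0351), epithelial junction and keratin genes (0.00993), interferon-stimulated genes (0.000169), NF-kB and inflammatory genes (0.0155), hypoxia and glycolysis genes (0.00232), unfolded protein and amino acid stress genes (1.48e-06), each with its adjusted p. The lists with higher ones were mitosis (0.00197) and YAP/TAZ target genes (0.00477). With an estimated correlation the adjusted p was 0.470 or more for each of the lists. A Notch list lost its call when NOTCH3 was left out of both Notch lists.

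Of the genes named in the text, a negative interaction (log2 scale, adjusted p under 0.05) was called for PTGES -7.20, FUT1 -6.44, LOC100130238 -6.41, PRRT4 -6.27, HERC5 -6.24, BCAM -6.04, MLXIPL -5.59, LIF -3.83, OAS3 -3.60, CDKN1C -2.81, F11R -2.66, DTX4 -1.94, PKP3 -1.88, P4HA2 -1.62, JAG2 -1.61, NOTCH3 -1.47, SLC2A1 -1.34, CHAC1 -1.29, ISG15 -1.17, SLC7A11 -1.16, LOXL2 -0.99, HYOU1 -0.99, CDKN1A -0.91, NOTCH1 -0.82, NRARP -0.82, ADAM17 -0.57. A positive one was called for ADAMTS6 5.33, KRTAP3-2 5.17, SHROOM2 4.84, ANKRD20A4 4.78, PCDH9 4.45, NDP 4.19, PLSCR4 1.99, FOXP2 1.99, CDKN2B 1.52, NT5E 1.39, TGFB2 1.15, CDKN1B 0.71. The sign is that of the difference between 2 log2 fold changes, so a positive value can be a weaker fall. With 1 library left out, the calls of 19 of these 38 genes were lost in at least 1 of the 8 fits (adjusted p = 0.0502 to 0.178): in all 8 for ADAM17, in 5 to 7 for NOTCH3, NOTCH1, NRARP, LOXL2, PRRT4, ANKRD20A4, KRTAP3-2, HERC5, CDKN1A, CDKN1C and SLC7A11, and in 1 to 4 for MLXIPL, PLSCR4, PTGES, ADAMTS6, DTX4, CDKN1B and NDP.

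Of the 1329 genes, 1250 had a log2 fold change of smaller size in the libraries labelled NOTCH3 shRNA and 79 of larger size, and this smaller response was weighed against technical explanations. A larger spread between those libraries would leave the size of the response. It could not lose calls in those libraries alone, since the fit gave both responses the same standard error per gene (median 0.189 in each). Over 2065 genes changed in experiment 2, HHEX left out, the slope of the response was 1.14 in control shRNA cells. It was 0.441 in the libraries labelled NOTCH3 shRNA, a ratio of 0.388. This argues against spread as the cause of the smaller size, and the test says nothing on lost calls. Of 1072 genes other than HHEX that were higher with the PRH virus in experiment 2 and in control shRNA cells, 22.7% already stood at or above the PRH virus level in the libraries labelled NOTCH3 shRNA. The 95% Wilson interval, which takes genes as independent though they are not, was 20.3% to 25.3%. The genes were also chosen by the PRH virus values that set this level, which can lower the percent. The limit of 25% set beforehand lies inside the interval, so this part stays open. Of 1309 genes other than HHEX that were higher in experiment 2, chosen without regard to their response in experiment 3, 656 started below their control level. Their response was still smaller, by a median of -0.25 on the log2 scale (bootstrap interval over genes, which are not independent, -0.30 to -0.21), with medians of 0.63 in the libraries labelled NOTCH3 shRNA and 0.91 in control shRNA cells. This argues against a level already reached as the cause for these genes. They were chosen by the empty virus values that both responses subtract. Such a choice can raise the response in the libraries labelled NOTCH3 shRNA and lower that in control shRNA cells. The medians and the slope are also unlike measures over different genes, so they do not show whether these genes kept more of the response than others. The starting level stays open as part of the cause over all genes. HHEX with the PRH virus was lower in the libraries labelled NOTCH3 shRNA (-2.25), so less PRH may account for some of it, which cannot be told apart from the shRNA or the cells because no group has matched HHEX; the shRNA itself stays open.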

How the results depend on the processing

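The replicate block, each library left out in turn, edgeR and DESeq2, the scalings, filters and pseudocounts were fixed before the data were examined, and edgeR with the block, the Notch lists without NOTCH3 and the lists without marker genes were added after. Over the alternatives, results that answer a comparison stayed the same 431 times. For a tested value this means the same direction and side of the threshold, and for a count of genes or lists a change by less than 1.5 times. Beyond that, 57 counts moved further, 11 values lost and 6 gained their call, and 4 reversed. Values of the other named genes stayed on their side 2345 times, lost their call 218 times, gained it 59 times and reversed 0 times. Unless stated otherwise, the cause was not tested. A fit with a lone library in a group assumes that it varies like the other groups.

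In experiment 1 the clone numbers are shared between groups, but nothing says that they mark a shared batch, and with 2 pairs the check decides little: deviations of same-numbered clones from their group means correlated with r = 0.582 (Spearman 0.656) across genes, which are not independent replicates. With the replicate block 10 genes passed for PRH knockdown, all lower, and 4 with edgeR and the block. POSTN and CALB2 then passed, at adjusted p-values of 0.0146 and 0.00371 with the block and 0.0152 and 0.00982 with edgeR and the block. The block left 8 lists called in place of 10, and changed the direction or call of no other gene named for PRH knockdown. No paired analysis was possible because the columns of experiments 2 and 3 carry no replicate number.

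With DESeq2 the calls were 703 for PRH knockdown, 1097 for the PRH virus in NOTCH3 shRNA cells and 2212 for the interaction, and the odds ratio of PRH knockdown against NOTCH3 shRNA was 287.711, where limma had no calls. Without the variance trend the calls fell to 758 in PRH overexpression, 2730 in control shRNA cells, 82 in NOTCH3 shRNA cells and 351 in the interaction. NOTCH3 then kept its interaction of -1.47 but not its call (adjusted p = 0.128), and 6 lists in control shRNA cells and 3 lists for NOTCH3 shRNA with the PRH virus were called. Without a filter PRH overexpression had 1382 calls. A 2-fold minimum, which only removes calls, left 778, 1738, 192, 4466, 3703 and 778 in the order of the comparisons after PRH knockdown. A fit with only the 4 libraries of the comparison left 3 calls for the PRH virus in NOTCH3 shRNA cells and an odds ratio of 7 with control shRNA cells, where it made 5017 calls in place of 4282. With an estimated correlation 0 lists were called in each of the 7 comparisons. With fry, which does not compare a list with other genes, the counts were 0 for PRH knockdown, PRH overexpression, the PRH virus in NOTCH3 shRNA cells and the interaction, 13 for the PRH virus in control shRNA cells, and 20 and 15 for NOTCH3 shRNA with the empty and the PRH virus.

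Leaving out 1 library gave 32 to 781 calls for PRH knockdown, 1314 to 2101 calls for PRH overexpression, 2208 to 2891 calls for the PRH virus in control shRNA cells, 1 to 376 calls for the PRH virus in NOTCH3 shRNA cells, 499 to 1155 calls for the interaction, 6322 to 7469 calls for NOTCH3 shRNA with the empty virus and 5677 to 6036 calls for NOTCH3 shRNA with the PRH virus. Lists called ranged over 6 to 10 for PRH knockdown, 3 to 6 for PRH overexpression, 6 to 10 for the PRH virus in control shRNA cells, 7 to 10 for the PRH virus in NOTCH3 shRNA cells, 4 to 7 for NOTCH3 shRNA with the PRH virus, 6 to 10 for the interaction and 7 to 8 for NOTCH3 shRNA with the empty virus. The NOTCH3 log2 fold change ran over -3.75 to -0.69 in PRH knockdown (called without PRH shRNA clone 2), -0.16 to 0.47 for the PRH virus in NOTCH3 shRNA cells (reversed to -0.10 without PRH virus library B and to -0.16 without empty virus library A), -0.24 to 0.40 for NOTCH3 shRNA with the empty virus (reversed to -0.24 without NOTCH3 shRNA library B and to -0.04 without control library A) and -1.79 to -1.16 in the interaction, called only without NOTCH3 shRNA + empty virus library A. Odds ratios of direction ran over 0.760 to 8.59 between PRH knockdown and PRH overexpression, 1 to 374 between PRH knockdown and NOTCH3 shRNA, and 3.00 to 213 between the PRH virus in control and in NOTCH3 shRNA cells. PRH overexpression was the shallowest experiment, where 13263 genes passed the filter against 15836 in experiment 3, and no alternative varied the depth. On simulated data the fit recovered 0% of 2-fold changes in PRH knockdown.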

Other observations

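The tests of explanations in this part and the marker genes were chosen after the results were seen, while the lists were fixed beforehand. Inhibitors of cell cycle kinases moved both ways with the PRH virus in experiment 2 and in control shRNA cells. In experiment 2, 2 of 8 rose, CDKN1A (1.77, adjusted p = 0.00121) and CDKN2D (1.33, adjusted p = 0.0139; 0.0608 without PRH virus library A), and 2 fell, CDKN1B (-0.86, adjusted p = 0.00883) and CDKN2B (-1.02, adjusted p = 0.00666), the same counts adjusted over the list alone. In control shRNA cells 3 rose and 4 fell, again the same counts adjusted over the list alone: CDKN1A had 1.36, CDKN1C 3.57, CDKN1B -1.01 and CDKN2B -1.96. In cells labelled NOTCH3 shRNA 0 rose and 0 fell (0 and 2 adjusted over the list alone). CDKN1A and CDKN1B encode p21 and p27, and CDKN2B encodes p15, an inhibitor of CDK4 and CDK6. Camera called the list in 0 of 7 comparisons (adjusted p = 0.288 to 0.967). Fry, which does not compare a list with other genes, called it lower with the PRH virus in control shRNA cells (adjusted p = 0.0223). It called the list higher for NOTCH3 shRNA with the empty virus (0.0132) and with the PRH virus (0.00222), and in no other comparison.

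Further lists were called by camera in none of the comparisons that tested them: EGF-family ligands, receptors and ERK targets (adjusted p = 0.0971 to 0.916), VEGF, endoglin and angiogenic genes (0.201 to 0.936) and hepatocyte markers (0.449 to 0.936). For NOTCH3 shRNA, fry called the EGF-family list higher with the empty virus (adjusted p = 5.97e-05) and the PRH virus (5.18e-05). It called the VEGF list higher with the PRH virus (0.0101) and hepatocyte markers lower with the empty virus (0.0443). Of 34 G1/S and DNA replication genes, 1 rose with the PRH virus in experiment 2 and 8 rose and 1 fell in control shRNA cells, and the list was not called in either (adjusted p = 0.612 and 0.102). The counts adjusted over the list alone were the same.

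In the libraries labelled NOTCH3 shRNA, epithelial genes were higher while NOTCH3 was not lower with the empty virus. The scaling of the libraries is argued against, since the median log2 fold change of the epithelial list was 7.99 after TMM rescaling. A 2-fold fall of the NOTCH3 transcript against the control libraries with the empty virus is argued against as well. The lower 95% bound of its change was -0.46, above the -1 that such a fall would give. If these are other cells, their own NOTCH3 level without the shRNA was not measured, so a fall from that level stays open. With the PRH virus, NOTCH3 was lower than in control libraries. Cells of another kind in these libraries could bring such a profile: 231 genes were abundant there and under 1% of that in control libraries, against 4 for the converse. In a check for mixed-up samples, which names no library, 4 of all 16 libraries stood far below the others in the genes checked. The count does not place these 4 among the libraries labelled NOTCH3 shRNA. Both another line and a derivative of this line would give such a mismatch. How much of the profile comes from the cells and how much from the shRNA cannot be told apart, because both libraries of each group share it, and an effect of the shRNA at the protein level stays open and untested.

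In the PRH shRNA libraries, epithelial genes lay higher, most in clone 2. A share of cells like those labelled NOTCH3 shRNA in experiment 3 is a candidate explanation. In clone 2, 85.3% of the 231 marker genes, chosen in experiment 3 alone, lay within 2-fold of a single ratio. The percent was 71.0% in clone 1 and 68.0% in each control clone, so it does not set clone 1 apart from the control clones. It was 11.7% to 49.4% in experiment 2 and in the control shRNA libraries of experiment 3, where the genes lie near 0. As a percent of their level in the libraries labelled NOTCH3 shRNA, the genes stood at a median of 45.0% (quartiles 34.6% to 56.1%) in clone 2 and of 9.47% (6.04% to 13.5%) in clone 1. The medians were 1.84% and 1.09% in the control clones, against 0.0718% to 0.281% in those other libraries. A low level of the profile in the control clones is therefore open too. Cells of this line that share an expression state would give the same values, so a mixture and a state are both open. Mixing into cells like the control clones could not by itself empty a gene, since the remaining share would keep its level. POSTN and HEY2 had log2 fold changes of -11.95 and -6.76 with clone 2 alone, and -10.66 and -7.11 with clone 1 alone. A mixture alone leaves these genes unexplained. They were picked for their small p and do not bear on the epithelial genes.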
